A study of Arabidopsis thaliana with 2 samples.

How the data were processed

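DNA methylation was measured by whole-genome bisulfite sequencing, in which unmethylated cytosines are converted and read as thymine, in 13-d-old seedlings of Arabidopsis thaliana, ecotype Col-0. There were 2 libraries, with 1 library for each genotype. SUCSUL carries the SUC2::SUL transgene in an otherwise wild-type background, and SUCSUL amp1lamp1 carries the same transgene with mutations in AMP1 and its paralogue LAMP1. Per the labels' protocols, sonicated DNA was ligated to methylated adapters before bisulfite conversion. The genome build was TAIR10, per the submitters' processing notes. The aligner, the methylation caller and any removal of duplicate reads are not given in the sources used here.

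The deposited tables list every cytosine with at least 1 read. Each deposited row gives the counts of methylated and unmethylated reads, a methylation level in percent computed by the authors, the sequence context and the trinucleotide. The tables held 40280562 cytosines in SUCSUL and 40505287 in SUCSUL amp1lamp1. The deposited percent matched the deposited counts in every row, to within 0.001 points, no cytosine was listed more than 1 time, and the highest depth was 101 reads in both libraries. An equal maximum in both looks like a ceiling set in the authors' processing, which the sources used here do not state; if so, depth is cut off in chloroplast DNA, where its mean was 87.3 to 89.3 reads. Over chromosomes 1 to 5, SUCSUL had a mean depth of 6.78 reads per cytosine listed in either library (median 6) and SUCSUL amp1lamp1 of 7.63 (median 7). At least 4 reads in both libraries were present at 66.1% of these cytosines. Reads carry no molecular identifiers, so the Wilson 95% intervals, and the limits that a count of 0 allows (3 counts of the total), cover counting error only. Each read is counted at every cytosine it covers, so these intervals and the Fisher tests below treat linked counts as independent and understate that error.

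Methylation levels were computed as methylated reads over all reads. Differences are SUCSUL amp1lamp1 minus SUCSUL, in percentage points. Differentially methylated bins of 100 bp were called separately in CG, CHG and CHH. Sites needed at least 4 reads in both libraries and bins at least 4 such sites. Bins were called at an adjusted p below 0.01 (2-sided Fisher's exact test on reads, Benjamini-Hochberg within a context) and a difference of at least 40, 20 or 10 points in CG, CHG or CHH. With 1 library per genotype, this test compares the libraries and not the genotypes. The test, thresholds and gene lists were fixed before the data were examined, and so were the alternative settings except those named below as chosen afterwards. The caller was tested on simulated data made from the depths of these bins, with 200 changed bins of low methylation at each size. In CG it recovered 41.0% of bins changed by 40.0 points and 97.0% of those changed by 60.0 points, among 439684 bins. In CHG it recovered 10.0% at 20.0 points and 39.5% at 30.0 points, among 505367 bins. In CHH it recovered 14.5% at 10.0 points and 50.5% at 15.0 points, among 1084258 bins. It called 0 unchanged bins in each of these runs. The simulated counts were independent and held no spread between libraries, so this does not give the rate of false calls in the real data.

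Genes came from a table of the assembly TAIR10.1, used for names and for assigning bins to genes, and its coordinates are not printed. All 72 genes of the 6 fixed lists were found in it. To check that the table and the deposited positions share coordinates, bases were rebuilt from the deposited trinucleotides, which recovered 68.1% to 70.4% of each chromosome. The conserved loop sequence of tRNA genes lay at its place before 1 end in 510 of 625 tRNA genes (81.6%), against 2.1% after a shift of 10 bp. The first form of that motif held bases that the rebuilding cannot recover and matched nothing, so unknown bases were then allowed at those places.

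Some analyses departed from the design. The table gives no strand, so both 1 kb flanks of a gene stand in for its upstream region, and no exons are named. It marks no transposable elements, so its 3917 pseudogene loci were used as a class, which does not separate transposon-derived genes. Pericentromeres were positions within 3 Mb of 15, 3.6, 14, 4 and 12 Mb on chromosomes 1 to 5. Endogenous inverted repeats were to be searched only in a reference genome, and none was used here. They were searched instead in the rebuilt sequence, with BLAST+ 2.17.0 in windows of 16 kb every 8 kb, for arms of at least 300 bp, at least 80% identity and a spacer of at most 5 kb. The first definition of identity counted a known base opposite an unknown one as a mismatch and gave 52 repeats. It was replaced, because a locus expected to hold a repeat was missing, by identity over pairs of known bases, which gave 125 repeats and still not that locus. No methylation value at repeats had been seen at that point, and the first definition is kept as an alternative. A search with shorter seed words did not finish and gave no result.

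The named regions are, per context and direction, the first 4 regions after merging called bins within 200 bp, ranked by number of called bins and then by difference; unless stated, their levels are over the called bins, at sites with at least 4 reads in both libraries. Named genes are the 4 transgene and mutated genes and each member of the other lists with a called bin. Named repeats are the 4 with the largest CHH rise and the 4 with the largest fall among those with at least 100 covered CHH sites. Levels of repeats are over their arms, without the spacer. The medians of gene lists and repeats were set against 10000 random sets matched on mean methylation, as a description of these libraries. Strands were also compared within each library, which measures technical noise and no spread between samples. The deep stretches at CHLI1 and SUC2 (adjacent bins at 2 or more times the median depth in both libraries) and the search for stretches without reads (at least 40 cytosines, with a mean depth of at least 3 in the other library) were chosen after the data were seen. The same holds for thinning each site to its lower depth in the 2 libraries, which gives both libraries the same sites with the same weights, for making the genome-wide CHH levels equal, for the bound of 3 times the median depth and for the limit of 1% that defines windows with many CG calls. Alternative settings covered coverage minimums, bin size, thresholds, depth filters, thinning, strands and correction for unconverted cytosines. The analysis used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9. Mitochondrial reads entered no comparison.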

Results

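Cytosine methylation was compared between 2 bisulfite libraries of 13-d-old Arabidopsis seedlings, 1 from SUCSUL and 1 from SUCSUL amp1lamp1. SUC2::SUL drives an inverted repeat against SUL, the magnesium chelatase subunit gene CHLI1, from the SUC2 promoter, which is active in phloem companion cells. AMP1 and LAMP1 encode related proteins that resemble carboxypeptidases, and the series addresses how AMP1 limits small RNAs made from inverted repeats. Mean depth over the cytosines of chromosomes 1 to 5 with a read in either library was 6.78 reads in SUCSUL and 7.63 in SUCSUL amp1lamp1. There were no replicates, so no difference has a replicate check.

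The libraries were first compared at DNA that carries no cytosine methylation. In phage lambda DNA, 0.310% of CHH reads were methylated in SUCSUL (Wilson 95% interval 0.292 to 0.328%, 362382 reads) and 0.292% in SUCSUL amp1lamp1 (0.276 to 0.308%, 432993 reads). In chloroplast DNA the CHH values were 0.286% and 0.288%. Lambda CG values were 0.257% and 0.260%, and lambda CHG values were 0.276% and 0.264%.

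The transgene target and the mutated genes were examined next. Reads aligned to CHLI1 (AT4G18480), on chromosome 4, showed a methylated stretch at 10202201 to 10202600 (TAIR10) inside the gene. These reads may include reads of the SUC2::SUL transgene, so the levels below may not be those of the endogenous gene. In this stretch CG methylation was 83.2% in SUCSUL and 84.0% in SUCSUL amp1lamp1. CHG methylation was 44.6% (95% interval 41.6 to 47.7%, 995 reads) and 50.7% (47.7 to 53.7%, 1060 reads). CHH methylation was 30.2% (28.7 to 31.8%, 3476 reads) and 34.2% (32.7 to 35.6%, 4139 reads). These totals count each sequenced read at every cytosine it covers, so the intervals are too narrow. Of 112 CHH sites with at least 4 reads in both libraries, 68 were higher in SUCSUL amp1lamp1 and 44 were lower. No bin of the stretch was called in any context. Its CHH difference of 3.96 points lay at the 76.1 percentile of 1683 windows of equal length and similar level elsewhere. Those windows were not matched on depth, and the wider counting error of shallower windows favours a central percentile. The stretch was also deep, at 5.12 times the median depth in SUCSUL and 5.05 times in SUCSUL amp1lamp1. The 2 kb flanks of CHLI1 had CHH levels between 0.123% and 0.342%.

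**Figure D1:**
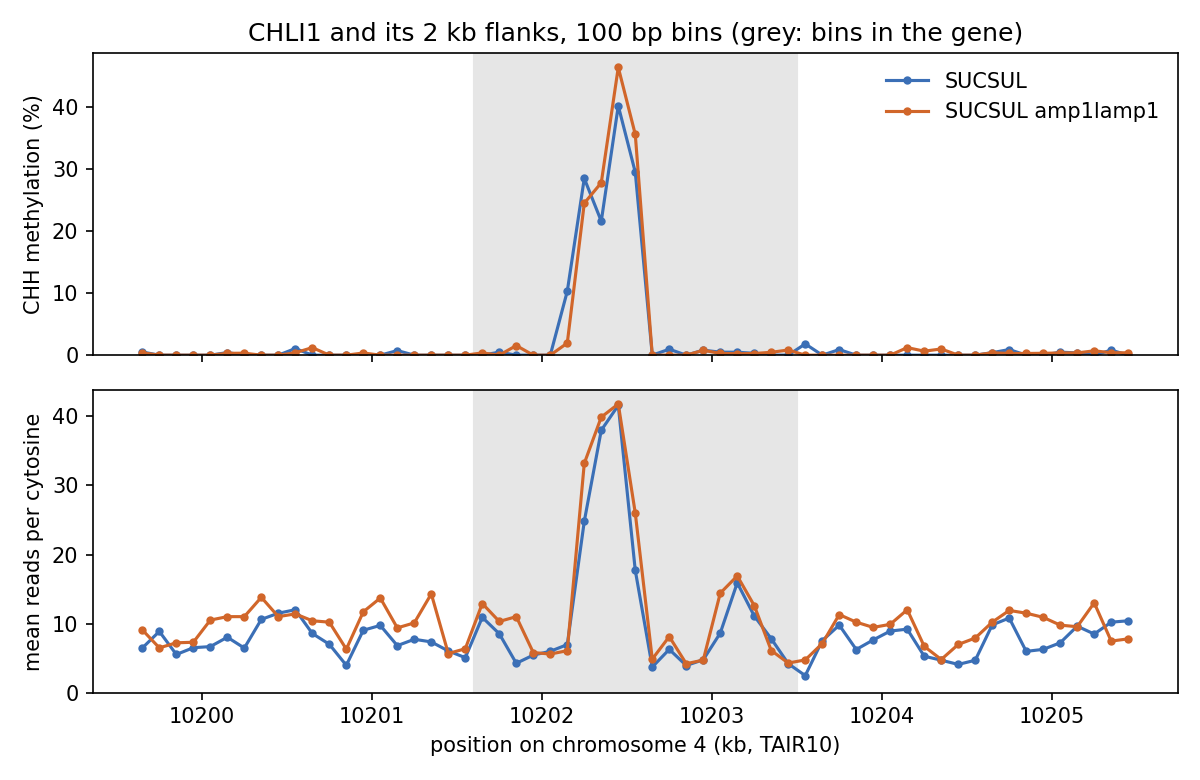
CHH methylation in percent (upper panel) and mean reads per cytosine (lower panel) in 100 bp bins across CHLI1 and its 2 kb flanks, against position on chromosome 4, with 1 line per library and the gene in grey. Both measures peak in the stretch from 10202201 to 10202600, where CHH methylation is 30.2% in SUCSUL and 34.2% in SUCSUL amp1lamp1.

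SUC2 (AT1G22710), the phloem sucrose transporter whose promoter drives the transgene, was almost unmethylated. Its gene body had CG levels of 0.436% in SUCSUL (1377 reads) and 0.401% in SUCSUL amp1lamp1 (1747 reads). Beside the gene, at 8033201 to 8033500 on chromosome 1, depth was 4.25 and 3.41 times the median while CHH methylation was 0.449% and 1.06%. AMP1 (AT3G54720) had gene-body CG levels of 11.3% (9.89 to 12.9%) and 9.02% (7.73 to 10.5%), a difference of -2.27 points that became -1.37 with at least 4 reads in both libraries, and depths of 1.03 and 0.916 times the median. In the 2 kb above the end coordinate of AMP1, CHH methylation was 6.36% in SUCSUL (5.48 to 7.38%) and 2.98% in SUCSUL amp1lamp1 (2.39 to 3.71%). LAMP1 (AT5G19740) had gene-body CG levels of 8.03% and 8.07%, a difference of 0.0361 points that became 0.195 at 4 reads. No bin in these 4 genes or their 2 kb flanks was called.

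Genome-wide, CHH methylation was lower in SUCSUL amp1lamp1 on all 5 chromosomes, at 2.682% against 2.937% over all of them. The difference of -0.255 points shrank to -0.0959 points when each site was thinned to the same depth in both libraries, and it kept its sign on each chromosome. CHG methylation was 9.970% in SUCSUL amp1lamp1 and 9.866% in SUCSUL, a difference of 0.104 points that became 0.617 points at equal depth. CG methylation was 27.39% and 27.81%, a difference of -0.422 points that turned to 0.458 points at equal depth. The direction of the CG difference therefore depended on how sites were weighted.

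The libraries were also compared by feature class. Pseudogene-class loci had higher CHG methylation in SUCSUL amp1lamp1, at 53.51% against 50.52%, and the pericentromeres had 34.99% against 33.23%. At equal depth these CHG differences were 3.30 and 2.33 points. Relative to SUCSUL, they were 6.55% and 7.06%, against 6.37% over all chromosomes. The relative CHG difference at equal depth was 6.54% in gene bodies, 3.88% in gene flanks and 4.05% in the arms. The larger differences in points therefore go with higher CHG levels. CHH methylation in the pericentromeres was 7.220% in SUCSUL amp1lamp1 and 7.669% in SUCSUL, and at pseudogene-class loci 10.41% and 10.94%. Their CHH differences at equal depth were -0.282 and -0.413 points. Bodies of protein-coding genes had CG levels of 16.42% in SUCSUL amp1lamp1 and 16.26% in SUCSUL, a difference of 0.165 points, and of 0.324 points at equal depth. The 1 kb flanks of protein-coding genes differed in CG by -0.736 points with all reads and by 0.456 points at equal depth. In the arms, the CG difference went from -0.0531 to 0.356 points and the CHG difference from -0.136 to 0.116 points. In the pericentromeres the CG difference went from -0.166 to 0.776 points. Reads were spread differently in the libraries: the ratio of SUCSUL amp1lamp1 to SUCSUL reads was 1.16 in gene bodies and 1.07 in the flanks.

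**Figure D2:**
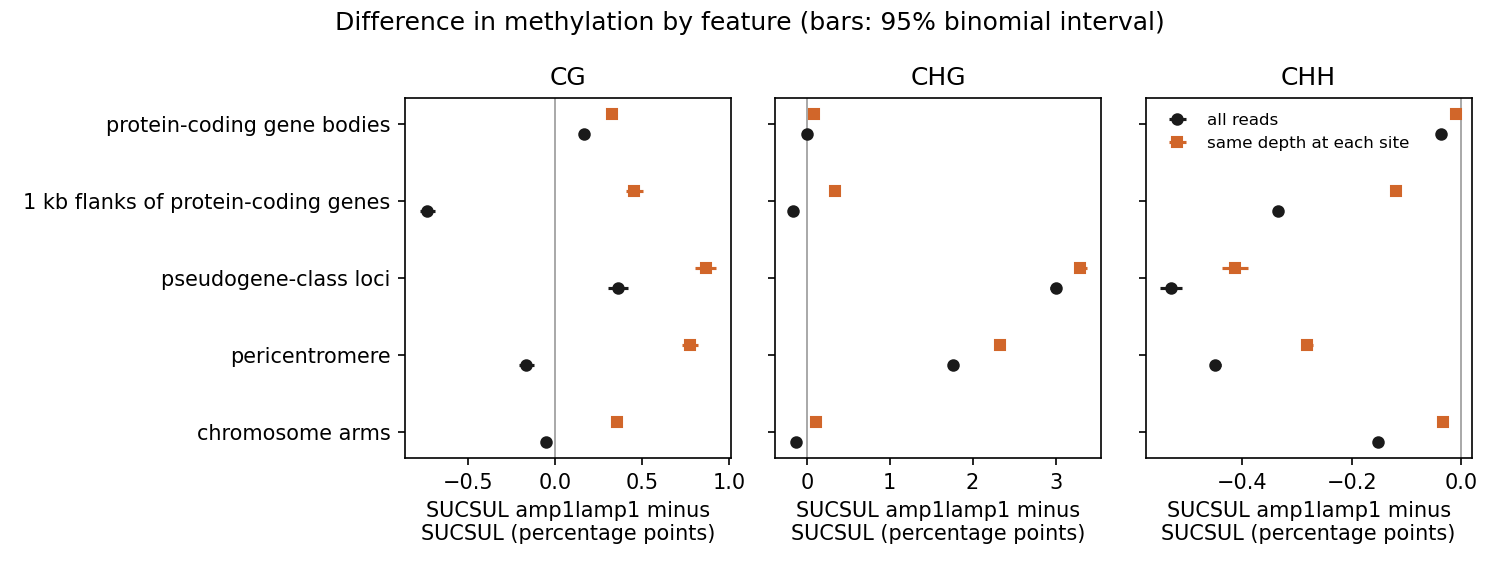
Difference in methylation between SUCSUL amp1lamp1 and SUCSUL in percentage points (horizontal axis) for 5 feature classes in CG, CHG and CHH, with all reads (circles) and with each site at the same depth (squares), and bars for the 95% binomial interval. CHG at pseudogene-class loci is higher by 3.0 points with all reads and 3.30 at equal depth, while CG in the flanks moves from -0.736 to 0.456.

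In the pericentromeres, CHH methylation was highest at the trinucleotides CAA and CTA, at 16.02% and 16.29% in SUCSUL and 15.45% and 15.72% in SUCSUL amp1lamp1. Relative differences with all reads were -3.54% at CAA and -3.51% at CTA, and -9.02% at CCT. At equal depth they were -2.96%, -2.93% and -3.68%, and those of the other CHH trinucleotides ran from -2.97% at CCC to -5.73% at CAT. In the arms, CAA was 2.147% and 1.930%, and the relative differences at CAA, CTA and CCT were -10.1%, -10.9% and -10.3% with all reads and -2.64%, -2.89% and -1.60% at equal depth.

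Local differences between the libraries were found in every context. In CG, 1619 bins were higher and 1496 lower in SUCSUL amp1lamp1, of 439684 tested. In CHG, 86 were higher and 25 lower, of 505367. In CHH, 490 were higher and 767 lower, of 1084258. With each site at the same depth in both libraries, 55 CHG bins were higher and 14 lower, and 265 CHH bins were higher and 372 lower. With a share of the methylated SUCSUL CHH reads set to unmethylated at random, so that the genome-wide CHH levels were equal, 763 CHH bins were higher and 388 lower, a setting that by its construction lowers every SUCSUL bin. Called CG bins lay mainly in bodies of protein-coding genes, which held 84.6% of the higher and 90.4% of the lower bins and 62.2% of those tested. Called CHH bins lay in gene bodies in 7.35% of higher and 8.21% of lower bins, while 56.3% of tested CHH bins did. Of the CHG bins, 43 were higher and 8 lower in pericentromeres, and 43 higher and 17 lower in the arms. There were 24 higher and 3 lower CHG bins in bodies of protein-coding genes, 20 and 14 in their flanks, 21 and 0 at pseudogene-class loci, and 21 and 8 elsewhere. Called CG bins were concentrated in blocks of the chromosomes. Of the windows of 1 Mb, 45 had calls in at least 1% of their tested CG bins, a limit chosen after the values were seen. They formed 7 runs, at 0 to 11 Mb on chromosome 1, 1 to 2 Mb on chromosome 2, 19 to 24 Mb on chromosome 3, 0 to 3 and 12 to 18 Mb on chromosome 4, and 0 to 10 and 13 to 22 Mb on chromosome 5. These windows held 37.8% of the tested and 84.2% of the called CG bins, with 1351 higher and 1271 lower. Calls were made in 1.58% of their CG bins, against 0.180% in the other 76 windows. Of the 4 transgene and mutated genes, SUC2 lies in the run on chromosome 1, AMP1 in that on chromosome 3 and LAMP1 in the first on chromosome 5, while CHLI1 lies in none. The same windows held 45.9% of the called and 39.0% of the tested CHG bins, and 31.3% of the called and 37.9% of the tested CHH bins. Of 27444 protein-coding genes, 3620 (13.2%) had a called bin in the body or 1 kb flanks.

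**Figure D3:**
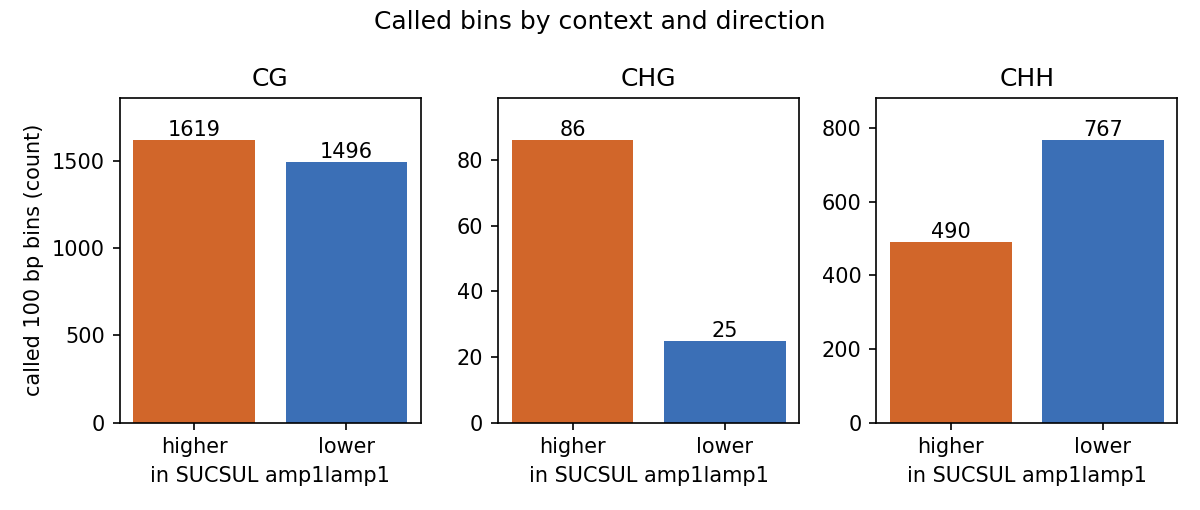
Number of called 100 bp bins (vertical axis, from 0, with a separate scale per panel) that were higher or lower in SUCSUL amp1lamp1 than in SUCSUL, in CG, CHG and CHH. CG bins are nearly balanced at 1619 and 1496, CHG bins are mostly higher at 86 and 25, and CHH bins mostly lower at 490 and 767.

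Calls between strands of the same library give the technical noise of the caller, and hold no spread between plants or libraries. On bins with at least 2 covered CG sites per strand, plus against minus gave 23 calls within SUCSUL and 56 within SUCSUL amp1lamp1, of 339834. The libraries compared on those bins gave 1199 calls on the plus strand alone and 1236 on the minus strand alone. In CHG the strand calls were 7 and 17 of 378291, and the libraries gave 31 on the plus and 28 on the minus strand.

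The regions with most called bins included several that differed in more than 1 context. Levels of these regions are over their called bins, which were selected for a difference, and over sites with at least 4 reads in both libraries. Most regions named here and in the next paragraph lie in the runs of windows with many CG calls. Those outside the runs are at AT4G13992, AT1G31030, CESA2 and AT1G75945 and near PKS1. The regions at AT1G31030 and CESA2 and near PKS1 lie in windows next to a run. Calls were made in 0.511%, 0.706% and 0.375% of the CG bins of those windows, against 0.180% over all 76 windows outside the runs. The pseudogene AT5G35935 (chromosome 5, 14088801 to 14089600) rose in CG from 8.82% in SUCSUL (306 reads) to 83.6% in SUCSUL amp1lamp1 (299 reads; lowest adjusted p 8.5e-17, Fisher's exact test). At 14089101 to 14089700 its CHG level was 0% of 312 reads, which allows up to 0.962%, and 39.6% of 341 reads. At 14089101 to 14089600 its CHH level was 0.200% and 17.7%. The gene AT4G13992 (chromosome 4, 8088001 to 8088900) rose in CG from 7.71% to 76.9% in 7 called bins. The pseudogene AT5G44925 (chromosome 5, 18143301 to 18144200) rose in CG from 21.8% to 90.8% in 6 called bins, and from 29.4% to 91.5% over the whole interval with all reads. At 18142901 to 18143400 it rose in CHH from 2.34% to 16.2%. The RNA gene AT4G02835 (chromosome 4, 2310101 to 2310600) rose in CG from 0.350% to 88.0%, and at 2309901 to 2310300 in CHG from 0.391% to 54.9%. CHG also rose at the pseudogene AT1G31030 (chromosome 1, 11066701 to 11067000), from 5.97% to 77.5%, and in AT1G30060 (chromosome 1, 10545201 to 10545500), from 1.1% to 48.5%. CHH rose near AT5G01280 (chromosome 5, 113701 to 113900) from 0% of 72 reads, which allows up to 4.17%, to 42.3% of 189 reads at sites with at least 4 reads in both libraries, and from 5.13% of 78 reads to 40.6% of 261 reads over all sites. Near the RNA gene AT2G00420 (chromosome 2, 1890001 to 1890200) CHH rose from 29.5% to 61.6%.

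Other regions were lower in SUCSUL amp1lamp1. CESA2 (AT4G39350), a cellulose synthase, had CG levels of 71.3% in SUCSUL (327 reads) and 0.627% in SUCSUL amp1lamp1 (319 reads) at 18300401 to 18301000 on chromosome 4 (lowest adjusted p 3.0e-49, Fisher's exact test). Near the lncRNA gene AT5G07295 (chromosome 5, 19830001 to 19830400) CG was 83.7% and 3.33%, and CHG 40.7% and 0.229%. AT1G02890 (chromosome 1, 648401 to 648700) had 68.3% CG methylation in SUCSUL and 0% of 182 reads in SUCSUL amp1lamp1, which allows up to 1.65%. AT1G75945 (chromosome 1, 28515901 to 28516200) had 65.2% and 0.433% in CG, and at 28515301 to 28515500 had 29.9% and 0% in CHG (0 of 174 reads, up to 1.72%). Near AT5G20100 (chromosome 5, 6789301 to 6789700) CHH was 34.6% and 0.258%. CHG there, at 6789301 to 6789500, was 55.1% and 0% (0 of 118 reads, up to 2.54%). Near AT2G04080 (chromosome 2, 1359901 to 1360100) CHG was 62.3% and 0% (0 of 156 reads, up to 1.92%). CHH was 27.1% and 0.136% near AGL83 (AT5G49490), a MADS-box gene (chromosome 5, 20076201 to 20076700). It was 26.8% and 0.60% in AT5G41530 (chromosome 5, 16611401 to 16611700). Near the phytochrome kinase substrate gene PKS1 (AT2G02950, chromosome 2, 856901 to 857100) it was 46.9% of 672 reads in SUCSUL and 0.417% of 240 reads in SUCSUL amp1lamp1. SUCSUL amp1lamp1 thus had fewer reads near PKS1, though it was the deeper library genome-wide.

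Genes of the methylation and small RNA machinery were examined as fixed lists. Over all 27444 protein-coding genes, 13.2% had a called bin in the body or 1 kb flanks. The counts per list, here and in the next paragraph, are small and were not tested against this share. Of the 9 listed genes with a called CG bin, 8 had theirs in the 7 runs of windows with many CG calls, and CMT2 had its calls outside them. Of 17 genes of RNA-directed DNA methylation, 2 had called bins. SHH1 (AT1G15215) rose in CG from 39.6% to 85.9% in 1 body bin, and KTF1 (AT5G04290) from 3.57% (28 reads) to 56.0% (25 reads). Of 13 genes of methylation maintenance and removal, 3 had called bins. The maintenance methyltransferase MET1 (AT5G49160) rose in 2 CG bins, from 0% of 60 reads (up to 5.00%) to 41.9%, and from 0% of 35 reads (up to 8.57%) to 41.5%. The chromomethylase CMT2 (AT4G19020) fell from 92.9% to 0% of 33 reads (up to 9.09%) in 1 CG bin and from 51.2% to 10% in another. SUVH4 (AT5G13960), a histone methyltransferase, rose in 1 CG bin from 40% to 80% and fell in another from 95.1% to 44.4%. Of 14 genes of small RNA production and action, 2 had called bins. The dicer gene DCL4 (AT5G20320) fell from 88.1% to 31.9% and from 52.9% to 0% in 2 CG bins of its body, and from 68.1% to 0% of 92 reads (up to 3.26%) in a flank. RDR1 (AT1G14790), an RNA-dependent RNA polymerase, rose from 13.0% to 62.4% and from 25.3% to 81.1%.

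Of 15 epiallele and imprinted loci, 2 had called bins: CHH in a flank of SDC (AT2G17690) fell from 25.5% to 7.33%, and CG in a flank of MEA (AT1G02580) rose from 0% of 34 reads (up to 8.82%) to 86.3%. Of 9 shoot meristem and leaf initiation genes, PHV (AT1G30490) alone had called bins, with CG falls from 92.9% to 43.5% and from 51.4% to 0% of 49 reads (up to 6.12%). The median CG difference of RNA-directed DNA methylation genes was 1.24 points, at the 89.3 percentile of random lists, and 0.473 points with at least 4 reads in both libraries. Those of the maintenance, small RNA, epiallele and meristem lists were 0.0440, -0.701, 0.236 and 0.145 points, at the 44.0, 14.4, 60.1 and 65.1 percentiles. With 2 kb flanks the first 3 of these became -0.426, -0.208 and 0.0114 points, and at 4 reads the maintenance and epiallele medians became -0.261 and 0.0145 points. The 4 transgene and mutated genes had a median CG difference of -0.956 points (11.4 percentile) and a median CHH difference of 0.146 points (97.9 percentile). That CHH median rests on SUC2 (0.290% to 0.474%) and LAMP1 (0.206% to 0.313%), over body and 1 kb flanks. These levels lie near the unconverted share of CHH reads in lambda DNA, 0.310% in SUCSUL and 0.292% in SUCSUL amp1lamp1. The CHH medians of the other 5 lists lay between the 22.4 and 78.2 percentiles, and the CHG medians of all 6 lists between the 6.27 and 57.9 percentiles.

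Endogenous inverted repeats were compared because they can be sources of double-stranded RNA. Whether these repeats give rise to small RNAs was not examined. Of 125 repeats, CHH methylation was higher in SUCSUL amp1lamp1 at 53 and lower at 72, with a median difference of -0.0757 points, at the 78.6 percentile of matched random sets. That median is the value of a repeat with CHH levels of 0.341% in SUCSUL and 0.266% in SUCSUL amp1lamp1. These levels lie near the unconverted CHH share in lambda DNA, 0.310% and 0.292%. At repeats with such low levels, the direction cannot be told from background. CHG was higher at 80 and lower at 45, with a median of 0.428 points (6.77 percentile), and CG was higher at 84 and lower at 40, with a median of 0.702 points (72.6 percentile). Pooled over the reads of all 125 repeats, the differences were -0.412 points in CHH (8.54% to 8.13%), 0.716 in CHG (29.4% to 30.1%) and -0.472 in CG (61.3% to 60.8%), so the CG direction depended on how repeats were weighted. The CHG median was 2.28 points for repeats of at least 90% identity and 2.01 points under the first, stricter definition of identity. These subsets were not set against random sets matched on level, and among feature classes larger CHG differences in points went with higher levels. The larger medians therefore do not show that closer repeats gain more CHG methylation. The longest of the named repeats, with arms of 3245 bp on chromosome 3 (1963723 to 1970450, overlapping AT3G06435 and AT3G06436), had CHH levels of 9.36% (8.73 to 10%) in SUCSUL and 15.1% (14.3 to 15.8%) in SUCSUL amp1lamp1. It held 3 called CHH bins, each higher in SUCSUL amp1lamp1. Called CHH bins that were higher lay in 6 of the 125 repeats, and lower ones in 3. Among the repeats with at least 100 covered CHH sites, the other 3 largest CHH differences upward are given as levels over both arms, untested. They were at repeats overlapping the pseudogene AT4G35400 (20.9% to 30.4%), near AT4G05240 (9.35% to 16.5%) and overlapping the cation exchanger gene CAX3 (64.2% to 71.3%). The repeat at CAX3 held 1 called CHH bin, higher in SUCSUL amp1lamp1. A repeat with 98 covered CHH sites, overlapping AT1G49680, had CHH levels of 26.8% and 37.6%, also untested, and held no called bin. The 4 largest downward were near AT3G11290 (48.7% to 33.2%), over the pseudogenes AT1G33450 and AT1G33460 (49.4% to 38.2%), over AT1G41680 and AT1G41690 (17.9% to 11.3%, with 1 called CHH bin, lower), and over AT2G06270 (17.0% to 13.7%).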

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

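Mitochondrial DNA entered no comparison, and its methylated share was above that of lambda DNA in both libraries. In CG, 13.3% of mitochondrial reads were methylated in SUCSUL and 12.3% in SUCSUL amp1lamp1. In CHG the values were 7.46% and 7.29%, and in CHH 1.60% and 1.44%.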

How the results depend on the processing

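Thinning every site to the same depth, equalising the genome-wide CHH levels and the deeper bound of the deep stretches were chosen after seeing the data. The stricter repeat identity was the first definition. It was replaced before any methylation value at repeats had been seen, and was then kept as an alternative. The other alternatives were planned. Of all the alternative values, 101 stayed within the main value's counting interval (for gene lists the spread over members, for relative depth 0.5) or within 1.5 times a main count, 65 moved beyond it, and 8 changed direction, counting bin counts and main values whose interval leaves out 0. Another 5 differences, small against their spread and counted among the 101, also changed sign: CHLI1 body CG from -0.259 to 0.173 at 4 reads, the SUC2 stretch CG from 0.0411 to -0.313 with the deeper bound and -0.539 at 4 reads, and the maintenance list's median CG from 0.0440 to -0.426 with 2 kb flanks and -0.261 at 4 reads. No paired analysis was possible because each genotype had 1 library, and for the same reason no library could be left out and no other split of the samples exists. Unless a cause is stated, the cause was not tested.

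With every site thinned to the same depth, the genome-wide differences were 0.458 points in CG (reversed), 0.617 in CHG and -0.0959 in CHH. Gene bodies then had 0.324, 0.0836 and -0.0105 points in CG, CHG and CHH, and gene flanks 0.456 (reversed), 0.334 (reversed) and -0.119. Pseudogene-class loci had 0.865, 3.30 and -0.413, pericentromeres 0.776 (reversed), 2.33 and -0.282, and arms 0.356 (reversed), 0.116 (reversed) and -0.0343. The mean of site levels gave 0.454 in CG (reversed), 0.611 in CHG and -0.0953 in CHH. With at least 4 reads in both libraries, CG was -0.391 and CHH -0.250 genome-wide. At 10 reads, CG was -0.263, CHG 0.250 and CHH -0.225. Without sites above the 99th percentile of depth, CG was -0.315, CHG 0.142 and CHH -0.238. Correction by lambda gave -0.238 in CHH, and by the chloroplast 0.124 in CHG.

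Among features, a minimum of 4 reads gave 0.188 (CG) and -0.0358 (CHH) in gene bodies, -0.654 (CG) and -0.327 (CHH) in flanks, 0.429 (CG) at pseudogene-class loci, 1.71 (CHG) in pericentromeres, and -0.0187 (CG), -0.116 (CHG) and -0.141 (CHH) in arms. Correction by lambda gave 0.0190 (CHG) and -0.0200 (CHH) in gene bodies, -0.319 (CHH) in flanks, -0.434 (CHH) in pericentromeres, and -0.125 (CHG) and -0.134 (CHH) in arms.

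The CG count of 3115 bins became 305 at 10 reads, 1757 with bins of 200 bp, 6028 with 1 covered site per bin, 5812 and 805 with the difference threshold halved or raised 1.5 times, and 2043 past the threshold on each strand. The CHG count of 111 became 29 at 10 reads, 193 at an adjusted p below 0.05, 67 below 0.001 and 69 with every site at the same depth. The CHH count of 1257 became 2184 at 1 read, 323 at 10 reads, 2645 below 0.05, 540 below 0.001, 578 on each strand, 637 (265 higher and 372 lower) with every site at the same depth, and 1151 with CHH levels made equal. That last setting gave 763 higher and 388 lower, but it lowers every SUCSUL bin by the whole genome-wide gap, so its construction favours this turn. With 1 read drawn per site, 0 bins were called in each context, as so few reads per bin remain.

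Depth over CHLI1 in SUCSUL amp1lamp1 was 1.58 times that of its own flanks, against 2.14 times the median. The median CG difference of the RNA-directed DNA methylation list was 0.473 points at 4 reads, and that of the small RNA list -0.208 with 2 kb flanks. The epiallele list had 4 of 15 members with a called bin in the body or 2 kb flanks, against 5007 of 27444 protein-coding genes. At inverted repeats, the median CG difference was 1.45 points at 90% identity and 1.95 with a spacer of at most 1 kb. The CHG median was 2.28 and 1.91 in these, and 2.01 with the stricter identity. These subsets are given without a percentile among random sets. Differences near the thresholds were mostly missed in the simulated data. A true change equal to the threshold often falls below it by counting error at any depth. Depth was not varied there, so these misses cannot be credited to depth alone.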

Other observations

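The correction by lambda DNA, as an alternative setting, and the counts per 1 Mb were planned; the other tests in this part, and the limit that sets apart the runs of windows, were chosen after the results they bear on had been seen. Called bins were unevenly spread along the chromosomes. In windows of 1 Mb, the share of tested CG bins that were called was 1.58% in 45 windows forming 7 runs and 0.180% in the other 76, and was highest, at 2.44%, between 18 and 19 Mb on chromosome 5. For CHH the shares in the same 2 sets of windows were 0.0960% and 0.128%, and the highest share was 0.478%, between 11 and 12 Mb on chromosome 3. Called CG bins in the runs were nearly balanced, at 1351 higher and 1271 lower, and the runs include AMP1 and LAMP1. The cause of the CG runs was not tested. With 1 library per genotype, an effect of amp1lamp1 on them cannot be told apart from any other difference between the lines.

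CHH methylation was lower in SUCSUL amp1lamp1 on each chromosome. Less complete conversion in SUCSUL as the whole cause is argued against by lambda DNA: after correction the difference was -0.238 points. A different mix of covered sites may account for most of it, since the difference was -0.0959 points with every site thinned to the same depth in both libraries. The remaining difference stays open, and an effect of the amp1lamp1 genotype or of another tissue makeup was not tested, as each genotype had 1 library.

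The deep, methylated stretch inside CHLI1 may hold reads of the SUC2::SUL transgene aligned to the gene. A stretch as long, at 2 or more times the median depth in both libraries, was held by 67 of 27444 protein-coding genes with their 2 kb flanks (0.244%), so such depth was rare among genes. Levels there would then mix the transgene and the endogenous gene. Another origin of the extra depth was not tested. More transgene copies in SUCSUL amp1lamp1 are argued against as the source of its higher CHH level, since the relative depth of the stretch was 1.02 times that in SUCSUL. At the deep stretch beside SUC2 the same ratio was 0.832, lower in SUCSUL amp1lamp1. Whether that stretch holds transgene reads was not tested. Ordinary spread between the libraries is another candidate explanation. The difference lay at the 76.1 percentile of windows matched on length and level, but not on depth. A minimum of 50 reads was enough for a window, so wider counting error favours a central percentile. The percentile therefore cannot decide this question. A biological effect of amp1lamp1 on the stretch stays open as well.

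In SUCSUL amp1lamp1 no read covered 712 cytosines between 17242673 and 17244591 on chromosome 5 (TAIR10), a stretch of 1919 bp overlapping the thioredoxin gene TRX3 (AT5G42980) and the ubiquitin-conjugating enzyme gene UBC18 (AT5G42990). Chance is argued against, since the next largest of the 10 stretches without reads in 1 library had 79 cytosines. Poor reading of this sequence is argued against too, since the same cytosines had a mean depth of 7.09 reads in SUCSUL, above its median of 6, while the search asked for only 3. In the other 9 stretches the library with reads had a mean depth of at most 4.55. A deletion or rearrangement in the amp1lamp1 line is a hypothesis that was not tested.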
